A study of Mus musculus with 70 samples.

How the data were processed

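Hippocampus was dissected from one hemibrain of each mouse, and poly-A selected RNA was sequenced in paired reads of 150 bases on a NovaSeq 6000, per the labels' protocols. The mice were APP23 transgenics (TG), which carry human APP with a mutation of familial Alzheimer disease under the Thy1 promoter, and non-transgenic littermates (NTG). They ate ad libitum (ALF) or had food for 6 h per day, from Zeitgeber time (ZT) 15 to ZT21 (time-restricted feeding, TRF). ZT0 is lights on and ZT12 is lights off. Per the labels, the mice were 6 to 9 months old when TRF began and 10 to 13 months old at sacrifice, at ZT0, ZT6, ZT12 or ZT18. The labels' protocols state random assignment to feeding and to the time of sacrifice. They also describe a knock-in line, which none of these samples carries. Sex was balanced by design, per the labels' protocols, but no sample's sex is given.

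Reads were trimmed with Trimmomatic on the Galaxy platform, per the labels' protocols. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the genome build GRCm38, without versions, settings or annotation. The deposited values are a normalized expression signal per gene, made by the authors by dividing the read count of each gene by one factor per library. Within a library all values were whole multiples of one step, within a tolerance of 0.01 of a step. With the step taken as 1 read, each library's reads over the listed genes ran from 27.9 to 47.1 M (median 37.2 M). The normalized totals ran from 35.0 to 42.4 M. The table holds 14260 gene symbols, of which 97.6% were found in the RefSeq table of the same build. The lowest mean of any gene was 40.8 normalized counts, so genes under some level had been removed before deposition, by a rule that is not stated. The step rests on all values of a library. Its low values alone, up to about 20 times the smallest, were enough to show it in only 2 of 70 libraries, so the values were not treated as read counts for the tests, and limma on log2 values was used. As an alternative, voom weights from the whole multiples were tried.

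The unit was 1 animal. The 70 libraries were taken as 69 animals, since 1 library of NTG on TRF at ZT12 carries the number of replicate 232 with an R. It was read as a second library of that animal, which the labels do not state, and both libraries were averaged. In chi-square per degree of freedom they differed about as much as libraries of different animals. That value weighs abundant genes most, and Rn45s, of ribosomal RNA, held 0.34% of library 232 and 4.63% of 232R. It therefore cannot tell a repeat from another animal. In correlation and in the SD of the log2 difference they were near the most alike pair of different animals. This reading is therefore not settled, and an alternative used library 232 only. Groups held 16 NTG on ALF, 16 NTG on TRF, 19 TG on ALF and 18 TG on TRF. At ZT0, ZT6, ZT12 and ZT18 they held 7, 1, 6 and 2 animals (NTG, ALF), 6, 2, 6 and 2 (NTG, TRF), 6, 4, 6 and 3 (TG, ALF), and 6, 4, 5 and 3 (TG, TRF). Only ZT0 and ZT12 had at least 5 animals in each group, so changes between times were tested between these.

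Values were taken as log2 of the normalized count plus 1. A filter on a mean of at least 10 normalized counts removed no gene. Every test across genes is limma's moderated test (limma 3.58.1 in R 4.3.3, with a variance trend and robust variances), 2-sided, with Benjamini-Hochberg adjustment over 14260 genes and a threshold of 0.05. All 69 animals shared one estimate of the spread. Genotype and feeding were tested in a model with 4 group means and a term for each time, and time of sacrifice by an F test over the 4 times in the same model. Changes from ZT0 to ZT12 within a group, and differences between groups in that change, came from a model with 16 means, one per group and time. Fold changes are differences of log2 means with their standard error (SE). Levels of single genes are mean normalized counts with the SD over animals. Counting error is small at this depth, so the spread between animals sets the precision.

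Before the data were examined, 35 gene lists were fixed: clock genes, pathways that respond to feeding, stress and neuronal activity, glial states and Alzheimer-related sets, and markers of the cell types and neighbouring tissues that a hippocampal dissection can hold. Each list was tested in 12 comparisons, 420 tests in all, with camera from limma at its preset correlation of 0.01, with camera at an estimated correlation between genes, and with fry, adjusted over the 35 lists of each comparison. Counts adjusted over the list alone are given beside those over all genes. The core clock list was also fitted with a cosine of 24 h, adjusted over its 20 genes. Whether genotype and feeding effects oppose each other was measured by their covariance across genes. For that value the TG animals on ALF, which enter both effects, were split at random into separate parts 100 times, and the groups were permuted 100 times within times of sacrifice.

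The genes named were set by a rule fixed before the data were examined. Per comparison they are the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 in the higher group, and for time the 20 smallest p. Where no gene passed, the 5 smallest p are named as not passing. Predicted genes, Riken clones, pseudogenes and sex-linked marker genes were left out. From a list with a camera adjusted p past the threshold, or at least 3 members called, up to 4 members of smallest p are named, and Thy1, App and the core clock list are always reported. Some genes that the rule covers are not reported here.

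The tests of 6 of the comparisons were run on simulated data with 200 genes changed by known folds among the 14260, and the other comparisons were not simulated. Camera at its preset correlation, the covariance and the cosine were tried on separate simulated values. For TG against NTG on ALF, 64.2% of genes changed 1.25-fold were recovered, 89.6% at 1.5-fold and 97.0% at 2-fold. For the genotype by feeding interaction these shares were 37.3%, 79.1% and 97.0%. For TRF against ALF in TG they were 73.1%, 97.0% and 98.5%. For the change from ZT0 to ZT12 in NTG on ALF they were 25.4%, 67.2% and 92.4%, and for the difference of that change between feedings in TG 5.97%, 44.8% and 77.3%. For time of sacrifice they were 83.6%, 94.0% and 98.5%. Unchanged genes called ranged from 5, for the difference of the change between feedings in TG, to 13, for TG against NTG on ALF. Each gene was simulated independently of the others. These shares therefore do not cover false calls from variation that real libraries share across genes.

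Alternatives covered the pseudocount, the filter, quantile normalization, array weights, the covariates, the animals and times that entered, and each animal left out in turn. Added after seeing the data were voom weights, a stricter filter on a mean of at least 200, the levels of the choroid plexus and of the myelin list as covariates, and fits without the 5 libraries of lowest correlation with the others.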

Results

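The hippocampal transcriptome was measured in 69 mice, 37 of them APP23 transgenics (TG) and 32 non-transgenic littermates (NTG). Within each genotype one group ate ad libitum (ALF, 19 TG and 16 NTG) and the other was held on time-restricted feeding (TRF, 18 TG and 16 NTG). The animals were killed at ZT0 (25), ZT6 (11), ZT12 (23) or ZT18 (10). Estimated reads over the 14260 listed genes ranged from 27.9 to 43.4 M per library in NTG on ALF, 30.5 to 43.2 M in NTG on TRF, 29.6 to 43.4 M in TG on ALF and 29.3 to 47.1 M in TG on TRF. The series asks whether restricting the hours of feeding restores brain transcription in this model of Alzheimer disease.

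Thy1, whose promoter drives the transgene, separated the genotypes in every animal. Its mean was 24712 ± 2651 normalized counts in NTG (SD, n = 32, range 14727 to 29068) and 136694 ± 17326 in TG (SD, n = 37, range 101986 to 171318). Thy1 lies on chromosome 9 (44043384 to 44048579, GRCm38). App, the mouse gene (chromosome 16, 84952666 to 85175255), had a mean of 56189 ± 4983 in NTG and 55680 ± 6035 in TG, and it did not pass the test under either feeding (adjusted p = 0.977 on ALF and 0.776 on TRF, limma). The human transgene is not among the listed genes. Whether the added Thy1 reads in TG come from the mouse gene or from the transgene was not tested. The rise of Thy1 is therefore not evidence of a change in the mouse gene.

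**Figure D1:**
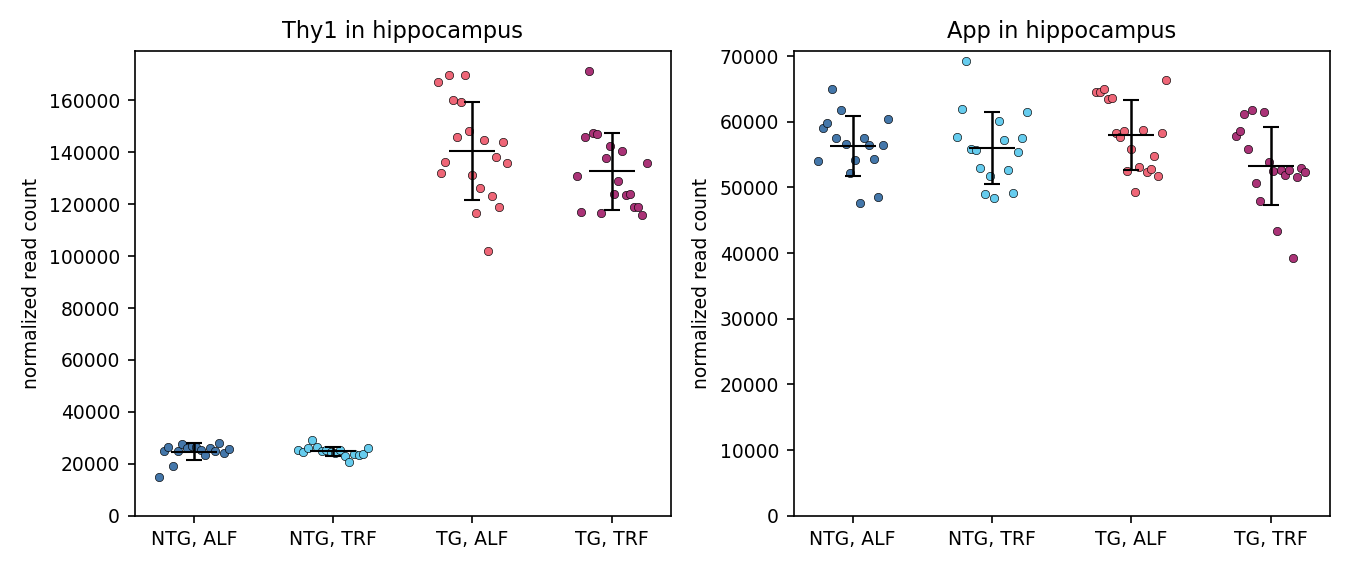
Normalized read counts of Thy1 and App in each of the 69 animals (points), by genotype and feeding, with the mean (bar) and SD (whiskers). Every TG animal has at least 101986 counts of Thy1 and every NTG animal at most 29068, while App overlaps between genotypes.

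The first comparison asks how the transgene changed the hippocampus under ad libitum feeding. Genes of cholesterol synthesis were higher in TG mice. Among the largest rises, after Thy1 (2.53 ± 0.06, log2 fold change ± SE, n = 19 and 16), were those of Stard4, a carrier of cholesterol (0.62 ± 0.07), Fdft1, the squalene synthase (0.46 ± 0.04), Nsdhl (0.44 ± 0.06) and Sqle, the squalene epoxidase (0.43 ± 0.04). They were followed by Msmo1 (0.42 ± 0.06), Hmgcs1 (0.41 ± 0.06), Fdps (0.41 ± 0.05) and Mvd (0.39 ± 0.09), all enzymes of the same pathway. In counts, Fdft1 averaged 3542 ± 394 in NTG and 4878 ± 505 in TG on ALF (SD). Lower in TG were Myom3 (−0.82 ± 0.19), Nrarp, a regulator of Notch signalling (−0.49 ± 0.06), Dio2, which activates thyroid hormone (−0.41 ± 0.08), Crhbp, which binds corticotropin-releasing hormone (−0.41 ± 0.07), the phosphatases Dusp6 (−0.40 ± 0.09) and Dusp4 (−0.33 ± 0.07), and the peptide gene Apln (−0.40 ± 0.07). Fam163a (−0.38 ± 0.08), Luzp2 (−0.30 ± 0.07) and Acsbg1 (−0.19 ± 0.05) completed the genes that fell. In all, 27 of 14260 genes passed, 17 higher and 10 lower, with adjusted p of the named genes between 2.0e-47 and 0.042 (limma, Benjamini-Hochberg). The balance of directions depends on the model, with 40 higher and 54 lower with array weights, 18 and 21 with the myelin level as a covariate, and 14 and 15 without the 5 libraries of lowest correlation with the others.

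Of the 22 measured genes of the cholesterol synthesis list, 22 had a positive value, 12 rose and none fell, with a median of 0.32 (camera adjusted p = 3.2e-67, and 1.8e-09 with an estimated correlation). Adjusted over the list alone, 18 rose. The astrocyte list had 1 of 14 values positive and a median of −0.14 (adjusted p = 0.0065 with an estimated correlation). Of its members only Acsbg1 fell over all genes, and 6 fell adjusted over the list alone. Members that missed the threshold were the glutamate transporter Slc1a3 (−0.15 ± 0.05), Fgfr3 (−0.17 ± 0.06) and S100b (−0.22 ± 0.08). The oligodendrocyte precursor list was also low, with a median of −0.096, 1 of 12 values positive and no member called over all genes (adjusted p = 0.011 with an estimated correlation). Fitted on ZT0 and ZT12 animals alone, the adjusted p of the astrocyte list was 0.091 with an estimated correlation.

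Lists tied to plaques and inflammation had positive medians with no member called. Of the plaque-induced list, 43 of 54 values were positive with a median of 0.095, including Cd68 (0.23 ± 0.08). Of the disease-associated microglia list, 19 of 27 were positive with a median of 0.089, and of the interferon list 17 of 17 with a median of 0.17. These lists passed camera at its preset correlation, but with an estimated correlation their adjusted p was 0.192, 0.347 and 0.252. The immediate early genes, which neuronal activity induces, had 28 of 32 values negative and a median of −0.17 (adjusted p = 0.192 with an estimated correlation), with Dusp6 called. Markers of choroid plexus, a neighbouring tissue, moved with the same contrast, with 19 of 19 values positive and a median of 1.67 (adjusted p = 0.215 with an estimated correlation). The list's level followed the first principal component of the animals (r = −0.99), which held 20.8% of the variance. With that level as a covariate 26 genes passed. Genes at an unadjusted p under 0.05 then numbered 675, against 1041 without it (limma).

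On TRF the same contrast of genotypes gave much of the same genes. Thy1 rose by 2.44 ± 0.06 (n = 18 and 16), and 12 of the 22 genes of cholesterol synthesis rose, among them Stard4 (0.51 ± 0.07), Fdps (0.45 ± 0.05), Fdft1 (0.44 ± 0.04), Mvd (0.43 ± 0.09), Nsdhl (0.39 ± 0.06), Sqle (0.36 ± 0.05) and Msmo1 (0.33 ± 0.06). Acat2, which makes acetoacetyl-CoA at the start of the pathway and stands outside the list, rose by 0.38 ± 0.05. The list's median was 0.28, with 22 of 22 values positive, and 20 rose adjusted over the list alone (adjusted p = 1.3e-08 with an estimated correlation). The genes that fell were Chrdl1, an antagonist of bone morphogenetic proteins (−0.54 ± 0.10), Crhbp (−0.39 ± 0.07), Luzp2 (−0.37 ± 0.07), Wwtr1 (−0.26 ± 0.06) and Jam2 (−0.25 ± 0.06). In all 19 genes passed, 14 higher and 5 lower (limma, adjusted p up to 0.048).

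The oligodendrocyte precursor list was low on TRF as well, with a median of −0.14 (adjusted p = 0.0027 with an estimated correlation). No member was called over all genes and 4 fell adjusted over the list alone, where Pdgfra (−0.21 ± 0.07), Sox10 (−0.22 ± 0.07) and Vcan (−0.25 ± 0.09) had the smallest p. The astrocyte list (median −0.08, with an estimated correlation adjusted p = 0.282), the interneuron list (−0.11, 0.130), the endothelium list (−0.16, 0.252) and the heat shock list (0.08, 0.130) passed only at the preset correlation. The choroid plexus list had a median of −0.26 here (adjusted p = 0.927 with an estimated correlation).

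Both sets of calls shared 15 genes, 13 higher in TG, Thy1 among them, and 2 lower, where independent lists would share 0.0167 and 0.0035. The animals of the 2 comparisons are different. Leaving Thy1 aside, 16 genes were called higher in TG on ALF. Of these, 15 were in the same direction on TRF and 12 were called, with a median of 0.40 on ALF and 0.35 on TRF. Of the 10 genes called lower on ALF, 10 were in the same direction on TRF and 2 were called, with medians of −0.40 and −0.23. None of these genes passed the test of genotype by feeding. Both sets were chosen by their calls on ALF, which favours larger values there. Smaller medians on TRF are therefore no measure of a feeding effect.

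**Figure D2:**
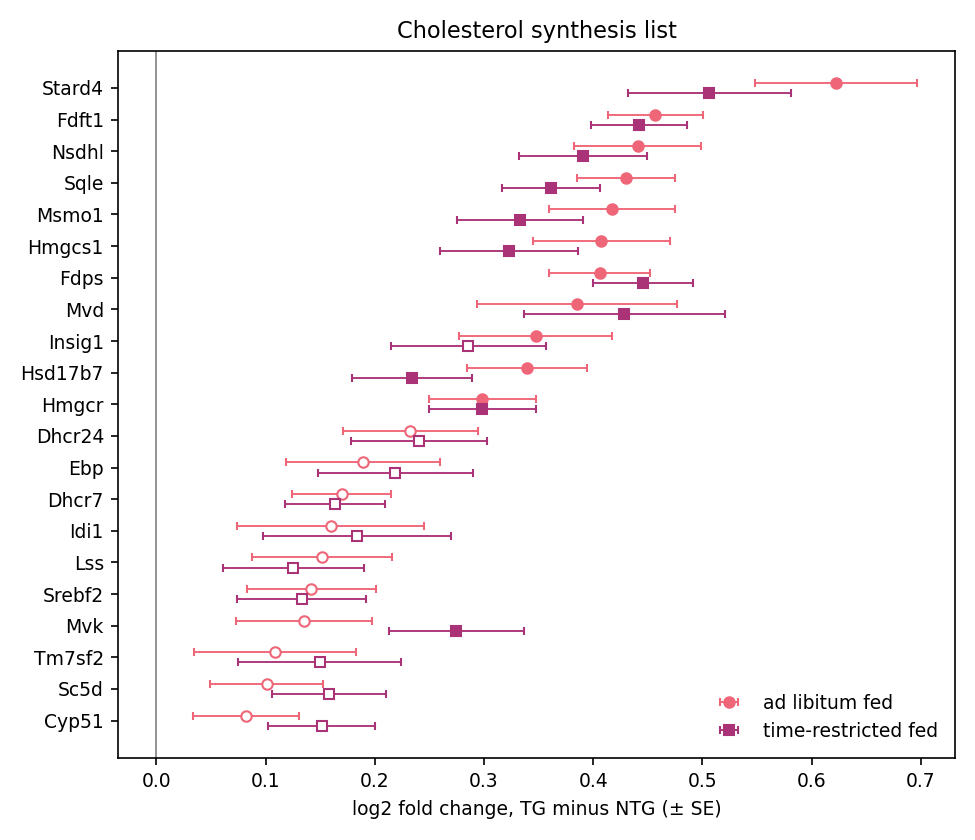
Log2 fold change of TG minus NTG (x axis, with SE) for members of the cholesterol synthesis list, on ad libitum feeding (circles) and on time-restricted feeding (squares). Filled symbols have an adjusted p under 0.05 in limma, and every value shown is positive under both feedings.

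The comparison of TRF with ALF in TG mice asks what feeding time changed in the transgenic hippocampus. The largest rises were in Etnppl, an enzyme of phosphoethanolamine breakdown (0.83 ± 0.14, n = 18 and 19), Sult1a1, a phenol sulfotransferase (0.63 ± 0.13), Tnnt2 (0.54 ± 0.13), Garin5a (0.52 ± 0.12) and Amn (0.51 ± 0.11). Kirrel2 (0.44 ± 0.11), Pxmp2, of the peroxisome membrane (0.37 ± 0.10), Rbm3, a cold-inducible RNA-binding protein (0.34 ± 0.07), Fam107a (0.34 ± 0.08) and Fkbp5, a co-chaperone of the glucocorticoid receptor (0.33 ± 0.07), also rose. Etnppl averaged 829 ± 260 normalized counts on ALF and 1491 ± 628 on TRF (SD). Lower on TRF were Enpp1 (−0.63 ± 0.15), the basement membrane gene Hspg2 (−0.61 ± 0.14), Fbxw15 (−0.57 ± 0.14), Dock5 (−0.54 ± 0.11), Serpinb1a (−0.51 ± 0.12) and Alpl (−0.50 ± 0.12). The endothelial receptors Cd93 (−0.46 ± 0.11) and Kdr (−0.44 ± 0.11), the collagen receptor Ddr2 (−0.44 ± 0.11) and the myosin Myo1d (−0.41 ± 0.10) fell too. In all 77 genes passed, 28 higher and 49 lower, with adjusted p of the named genes between 0.0012 and 0.046 (limma, Benjamini-Hochberg).

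Genes that respond to glucocorticoids had 21 of 22 values positive in TG mice on TRF, with a median of 0.31. Sult1a1, Fkbp5, Fam107a and Gjb6 (0.29 ± 0.07) rose over all genes, and 12 rose adjusted over the list alone. The list passed camera at its preset correlation (adjusted p = 1.4e-10), with adjusted p = 0.154 with an estimated correlation, while fry, which asks only whether the genes move one way, gave an adjusted p of 0.010. The oligodendrocyte and myelin list had 18 of 18 values negative and a median of −0.20. Over all genes 1 member fell, and 11 fell adjusted over the list alone. Its adjusted p was 0.233 with an estimated correlation and 0.028 by fry. Rbm3 was the called member of the cold-inducible list, whose median was 0.24 (adjusted p = 0.080 with an estimated correlation), with Cirbp at 0.28 ± 0.08.

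Other lists passed at the preset correlation without holding at an estimated one. The endothelium list had a median of −0.16, with Kdr called (adjusted p = 0.233 with an estimated correlation). The list of amyloid precursor processing and risk genes had a median of −0.08 and no member called (adjusted p = 0.080 with an estimated correlation), with Cd33 at −0.27 ± 0.08 and App at −0.12 ± 0.05. All 27 genes of the respiratory chain list were positive, with a median of 0.14 and no member called (adjusted p = 0.566 with an estimated correlation). The homeostatic microglia and plaque-induced lists had medians of −0.06, and Olfml3, a member of both, fell (−0.29 ± 0.07, adjusted p = 0.617 for either list with an estimated correlation). The cholesterol synthesis list had a median of −0.005 and no member called in TG on TRF against ALF (adjusted p = 0.979 with an estimated correlation). Choroid plexus markers moved with this contrast, opposite to their direction between genotypes on ALF, with 19 of 19 values negative and a median of −1.41 (adjusted p = 0.617 with an estimated correlation).

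The count of 77 is sensitive to the animals and the model. With the number series as a covariate it was 52, with 31 higher and 21 lower and 37 of them among the 77, and voom gave 15 higher and 86 lower. The count was 0 with ZT0 and ZT12 animals alone (1280 genes at an unadjusted p under 0.05, limma), 2 without a term for time, 20 with the choroid plexus level and 13 with the myelin level as a covariate (11 higher), and 7 (5 higher) without the 5 libraries of lowest correlation with the others, while array weights gave more, with 177 genes lower alone. Of these 5 libraries 4 are ALF animals at ZT0 (NTG_ALF_1, NTG_ALF_107, TG_ALF_5 and TG_ALF_16) and 1 is TG_TRF_104 at ZT12, so leaving them out takes animals from one side of several contrasts. Leaving out 1 animal gave 18 (without TG_TRF_104) to 248 (without TG_TRF_24).

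In NTG mice TRF changed few genes past the threshold. Banp (−0.43 ± 0.08), the peptide gene Apln (−0.38 ± 0.08), P4ha1, which hydroxylates collagen (−0.33 ± 0.07), and Ypel2 (−0.29 ± 0.06) fell, and no gene rose (n = 16 and 16, limma, adjusted p from 0.022 to 0.044). The cold-inducible list was higher on TRF, with 4 of 4 values positive and a median of 0.24 (adjusted p = 0.0096 with an estimated correlation). Cirbp (0.37 ± 0.09) and Rbm3 (0.31 ± 0.08) passed adjusted over the list alone, not over all genes. The glucocorticoid list had 18 of 22 values positive and a median of 0.15 (adjusted p = 0.539 with an estimated correlation), with Sult1a1 at 0.52 ± 0.14 and Txnip at 0.40 ± 0.13. The heat shock (median −0.05) and immediate early gene (−0.11) lists each had adjusted p = 0.474 with an estimated correlation. Of the 4 genes, none was among the 77 of TG mice. Independent lists would share 0.0137 lower genes, so the lack of overlap says nothing about a difference between genotypes. The count was 0 without a term for time (968 at an unadjusted p under 0.05, limma) and 0 without the 5 libraries named above (1027), and leaving out 1 animal gave 0 to 8.

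**Figure D3:**
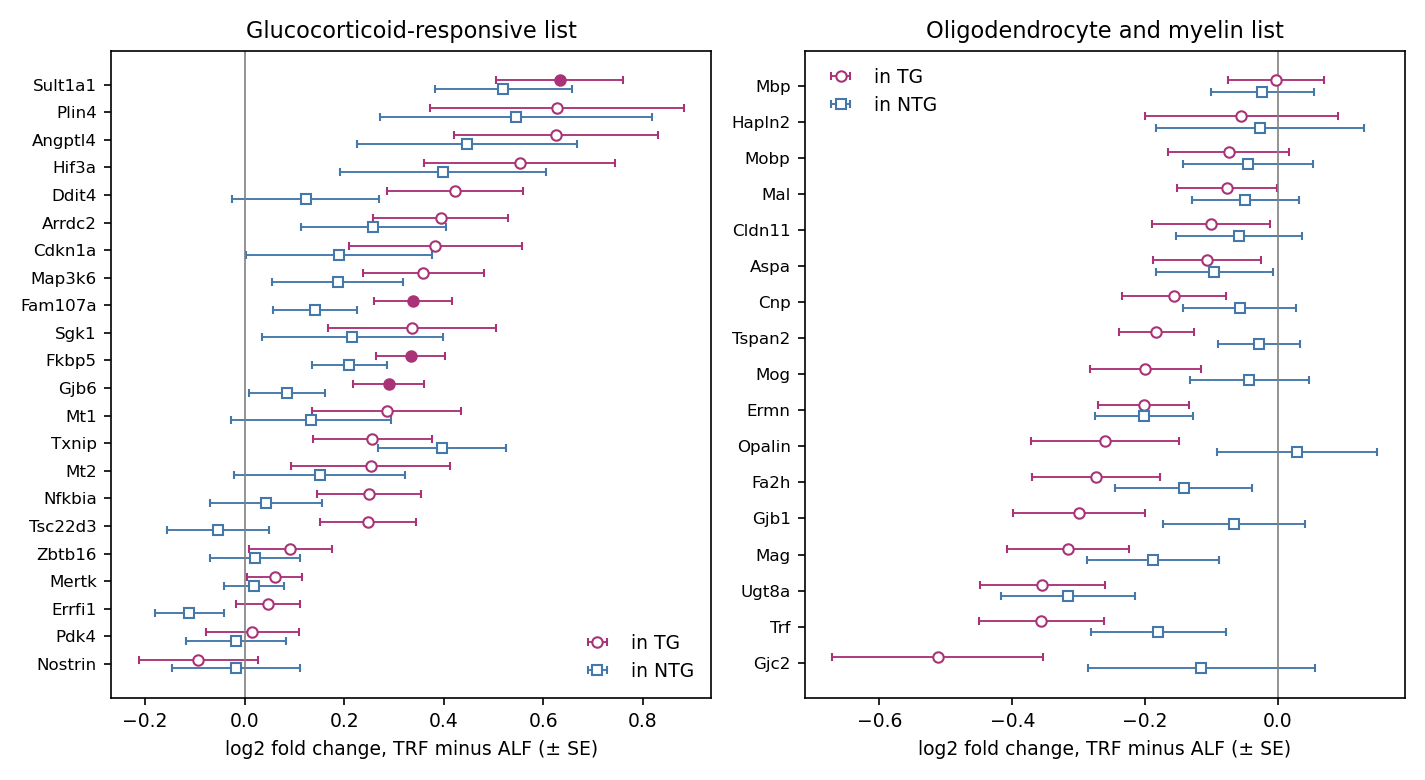
Log2 fold change of TRF minus ALF (x axis, with SE) for members of the glucocorticoid-responsive list (left) and the oligodendrocyte and myelin list (right), in TG mice (circles) and NTG mice (squares). Filled symbols have an adjusted p under 0.05 in limma, and the whole lists have medians in TG of 0.31 (left) and −0.20 (right).

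Whether feeding acted differently in TG and NTG mice was tested by the interaction of genotype and feeding. No gene passed (0 of 14260, limma, with 745 at an unadjusted p under 0.05). The smallest p were those of Spata6 (−0.68 ± 0.17), Cd274 (−0.59 ± 0.15), Sbk3 (−0.78 ± 0.21), Rdh13 (0.22 ± 0.06) and Pbx2 (0.21 ± 0.06), each with an adjusted p of 0.929. Of the immediate early genes 31 of 32 had a positive interaction, with a median of 0.24 (adjusted p = 0.309 with an estimated correlation), where Dusp6 was at 0.35 ± 0.12. The choroid plexus list had a median interaction of −1.88 (adjusted p = 0.424 with an estimated correlation). Under both genotypes the glucocorticoid, cold-inducible and myelin lists had medians of the same sign, and their interaction was not past the threshold with an estimated correlation.

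Across all genes, the effect of feeding in TG ran against the effect of genotype on ALF. With separate TG animals on ALF for each effect, the covariance of both log2 fold changes was −0.0082 (r = −0.32 across genes, which are not independent replicates), and it was negative in 100 of 100 random divisions of those animals. Permuting the groups gave a mean of 0.000295 and a range of −0.0150 to 0.0050, with 1 of 100 permutations as low. The covariance was −0.0051 without the choroid plexus, ependyma and meninges lists. It was 0.0027, no longer negative, once the level of the choroid plexus list was removed from each gene.

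Time of sacrifice was associated with more genes than genotype or feeding. Over the 4 times 5073 of 14260 genes passed (limma F test), of which 1521 peaked at ZT0, 1158 at ZT6, 1142 at ZT12 and 1252 at ZT18. Dbp, a transcription factor driven by the clock, averaged 891 ± 170 normalized counts at ZT0 (SD, n = 25) and 2460 ± 260 at ZT12 (n = 23), and the repressor Ciart 269 ± 64 and 748 ± 173. Bmal1, the clock's activator, went the other way, from 1385 ± 146 at ZT0 to 934 ± 100 at ZT12. The genes of smallest p that were higher at ZT12 than at ZT0 were Dbp (log2 1.49), Ciart (1.48), Rbm3 (0.97), Cirbp (0.88), Fmo2 (1.73), Tspan4 (0.71), Mthfd1l (0.67), Pla2g4e (0.77), Armcx5 (0.61) and Nr1d2, a clock repressor (0.49). Lower at ZT12 were the endoplasmic reticulum chaperones Calr (−0.60), Hspa5 (−0.63), Pdia6 (−0.48) and Hsp90b1 (−0.52), the co-chaperones Stip1 (−0.38) and Dnaja4 (−0.30), the matrix protease Mmp14 (−0.94), Bmal1 (−0.57), Glt8d2 (−0.62) and Ccdc190 (−0.76).

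The share of genes that passed varied between the lists, and so did the times of their highest means. Neither was tested between lists or against all genes, of which 5073 of 14260 passed. Of the clock list 17 of 20 passed, with peaks at all 4 times (4, 1, 7 and 5 genes at ZT0, ZT6, ZT12 and ZT18). Of the chaperone list of the endoplasmic reticulum 19 of 22 passed, 10 with a peak at ZT18 and 8 at ZT0, and of the heat shock list 16 of 20, 10 with a peak at ZT18 and 6 at ZT0. Of the immediate early genes 25 of 32 passed, 12 with a peak at ZT0 and 11 at ZT6. Fos averaged 680.3 ± 377 at ZT0, 693 ± 255 at ZT6 and 201.7 ± 81.7 at ZT12. Of the glucocorticoid list 17 of 22 passed, 13 with a peak at ZT12, the onset of the dark phase. Of the cholesterol synthesis list 19 of 22 passed, 16 with a peak at ZT6. Of the choroid plexus list none of 19 passed. All ZT6 and ZT18 animals carry numbers from 300 upward, a series that holds 2 animals at ZT0 and 1 at ZT12. The contrasts of ZT12 with ZT0 and of ZT18 with ZT6 together called 3997 of the 5073 genes, and 4176 with the number series in the model. Neither sets ZT6 or ZT18 against ZT0 or ZT12, so they do not test which time holds the peak. The contrast of ZT6 and ZT18 with ZT0 and ZT12, which largely crosses the series, called 545 genes (limma).

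A cosine of 24 h passed for 18 of the 20 clock genes over all animals, adjusted over the list alone, with Rora among those that did not pass (adjusted p = 0.258). Amplitudes on the log2 scale were 0.75 for Dbp with a peak at ZT 11.5, 0.74 for Ciart (11.5), 0.43 for Per2 (15.0), 0.30 for Bmal1 (1.32) and 0.41 for Nfil3 (23.8). Within groups it passed for 7 genes in NTG on ALF, 10 in NTG on TRF, 14 in TG on ALF and 13 in TG on TRF. No clock gene's cosine differed between genotypes or feedings past the threshold (lowest adjusted p = 0.228, for Per2, Nr1d2 and Bhlhe40 between genotypes on ALF).

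**Figure D4:**
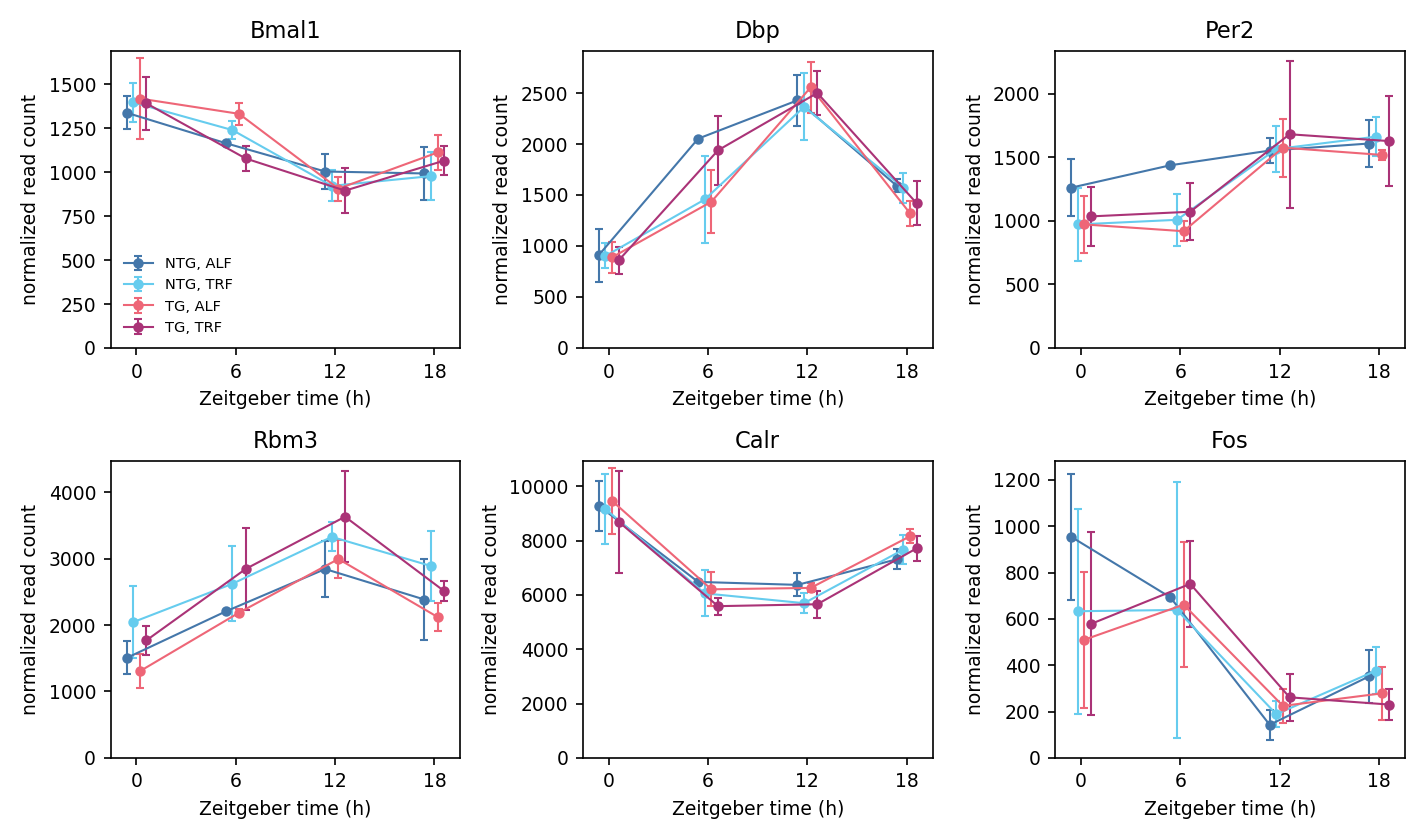
Normalized read counts of 6 genes at ZT0, ZT6, ZT12 and ZT18 (x axis, in h) in the 4 groups (colours), as means with SD; NTG on ALF has 1 animal at ZT6 and no error there. Over all animals Dbp goes from 891 at ZT0 to 2460 at ZT12 and Bmal1 from 1385 to 934.

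The change from ZT0 to ZT12, the start to the end of the light phase, was tested in each group. In NTG on ALF 310 genes passed (176 of them lower, n = 6 at ZT12 and 7 at ZT0, limma), in NTG on TRF 85 (51 lower, n = 6 and 6), in TG on ALF 316 (172 lower, n = 6 and 6) and in TG on TRF 506 (295 lower, n = 5 and 6). Leaving out 1 animal gave 147 to 595 genes in NTG on ALF, 53 to 97 in NTG on TRF, 1.1e+02 to 457 in TG on ALF and 236 to 680.0 in TG on TRF, and without the 5 libraries of lowest correlation with the others the counts were 130.0 and 143 in NTG on ALF and on TRF, and 1.3e+02 and 369 in TG. With voom weights more genes were higher than lower in NTG on TRF (37 and 29), in TG on TRF (264 and 198) and, narrowly, in TG on ALF (99 lower of 201), as they were in TG on ALF without the 5 libraries (69 and 60). The 4 counts were not tested against each other. The same 36 genes passed in all 4 groups, 14 higher and 22 lower. Dbp rose by 1.39 to 1.55 in the 4 groups, Ciart by 1.12 to 1.89, Fmo2 by 1.59 to 2.11, and Hif3a, a glucocorticoid-responsive factor, by 1.40 to 2.23. Rbm3 rose by 0.74 to 1.22 and Cirbp by 0.68 to 1.03, and the cold-inducible list passed in all 4 groups (adjusted p from 0.000467 to 0.0033 with an estimated correlation). Calr fell in each group, with −0.54 in NTG on ALF and −0.68 in NTG on TRF as its extremes, and Mmp14, Hspa5, Stip1 and Hsph1 fell in each as well.

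In NTG on ALF the genes that fell most were immediate early genes. Egr2 (−3.21 ± 0.59), Fos (−2.78 ± 0.43), Npas4 (−1.74 ± 0.27), Arc (−1.42 ± 0.38), Fosb (−1.33 ± 0.23), Egr1 (−1.18 ± 0.24) and Dusp1 (−1.04 ± 0.20) fell, with Apold1 (−1.18 ± 0.31), Ccn1 (−1.01 ± 0.23) and Mmp14 (−0.998 ± 0.15). Of the list's 32 members 12 fell, with a median of −0.56 (adjusted p = 0.026 with an estimated correlation). Rises beyond those shared by all groups were in Inmt (2.02 ± 0.49), Plin4, a coat protein of lipid droplets (1.46 ± 0.41), Rtl3 (1.38 ± 0.35), Cstad (1.29 ± 0.31), Baiap2l2 (1.06 ± 0.27) and Ifit3 (1.02 ± 0.23). The endoplasmic reticulum chaperones had 8 members fall and a median of −0.24, and the heat shock list 5 with a median of −0.19 (adjusted p = 0.055 for either with an estimated correlation).

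In NTG on TRF the chaperone lists were lower at ZT12. The heat shock list had a median of −0.20 with 4 members called (adjusted p = 0.0033 with an estimated correlation), among them Hspb1 (−1.08 ± 0.24) and Hspa1b (−0.59 ± 0.14). The endoplasmic reticulum list had 5 members fall and a median of −0.19 (adjusted p = 0.011 with an estimated correlation), including Hspa5 (−0.66 ± 0.12) and Pdia6 (−0.49 ± 0.09). The clock list had a median of 0.18 with 5 members higher and 2 lower (adjusted p = 0.0093 with an estimated correlation). Nr1d2 rose (0.51 ± 0.08), and Bmal1 (−0.60 ± 0.09) and Nfil3 (−0.71 ± 0.17) fell. Inmt (1.99 ± 0.51), Baiap2l2 (1.08 ± 0.28), Asb11 (0.94 ± 0.23), Tsc22d3 (0.88 ± 0.16) and Wnt9a (0.74 ± 0.18) rose, and Npas4 (−1.17 ± 0.28), Slc15a3 (−1.13 ± 0.25), the histone gene H2bc6 (−1.07 ± 0.24), Cldn5, of the tight junctions of vessels (−0.92 ± 0.21), and Dlx1as (−0.64 ± 0.14) fell. Dlx1as runs antisense to Dlx1, and reads of the pair cannot be told apart without strand.

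In TG on ALF the collagens Col3a1 (−1.56 ± 0.38) and Col1a1 (−1.14 ± 0.28), the transporter Slc6a13 (−1.22 ± 0.31), Vstm4 (−1.29 ± 0.21), Olfml2a (−1.11 ± 0.28) and Hspg2 (−1.05 ± 0.26) fell. The meninges and fibroblast list, which holds both collagens and Slc6a13, had 3 members fall and a median of −0.73, with adjusted p = 0.349 with an estimated correlation, and the choroid plexus list had a median of −1.78 (adjusted p = 0.621 with an estimated correlation). Mmp14 (−1.14 ± 0.16), Npas4 (−1.17 ± 0.28), Creb5 (−1.09 ± 0.28) and Slc15a3 (−1.01 ± 0.25) fell too. Rises were in Plin4 (1.91 ± 0.42), Rtl3 (1.49 ± 0.36), Scgn (1.34 ± 0.33), Rbm3 (1.22 ± 0.13), Plekhf1 (1.21 ± 0.33) and Garin5a (1.08 ± 0.21). Of the glucocorticoid list 5 members rose, with a median of 0.38 (adjusted p = 0.287 with an estimated correlation). The endoplasmic reticulum list had 8 members fall and a median of −0.23 (adjusted p = 0.103 with an estimated correlation).

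In TG on TRF 15 of the 22 glucocorticoid-responsive genes rose, with 22 of 22 values positive and a median of 0.79 (adjusted p = 0.0033 with an estimated correlation). Plin4 rose by 2.95 ± 0.44, Fkbp5 by 0.80 ± 0.12, Hif3a by 2.23 ± 0.34 and Tsc22d3 by 1.05 ± 0.17. The homeostatic microglia list had 16 of 16 values negative and a median of −0.27, with 4 members called (adjusted p = 0.045 with an estimated correlation), among them Itgam (−0.58 ± 0.11), the fractalkine receptor Cx3cr1 (−0.51 ± 0.11) and P2ry13 (−0.71 ± 0.15). The clock list had a median of 0.29, with 8 members higher and 2 lower (adjusted p = 0.0074 with an estimated correlation). Of the clock genes, Dbp, Ciart, Nr1d2, Bmal1 and Nfil3 passed in all 4 groups. The clock list's change did not differ between feedings past the threshold with an estimated correlation, in TG or in NTG. Other rises were in Gabrr2 (2.14 ± 0.39), Galnt15 (1.74 ± 0.33), Xdh (1.48 ± 0.23), Epha8 (1.32 ± 0.26) and the glucose transporter Slc2a4 (1.30 ± 0.36). Falls were in Casq2 (−1.50 ± 0.26), Chst3 (−1.33 ± 0.23), Ciita (−1.17 ± 0.28), Fabp7 (−1.14 ± 0.24), Erich5 (−1.13 ± 0.24), Slc15a3 (−1.10 ± 0.27), H2bc6 (−1.07 ± 0.26), Adam8 (−1.05 ± 0.27), Creb5 (−1.01 ± 0.29) and Apobec1 (−1.0 ± 0.28).

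The groups' changes from ZT0 to ZT12 were then compared directly. No gene's change differed between TG and NTG on ALF (0 genes, 2.27% of all genes at an unadjusted p under 0.05, limma), between feedings in TG (0, 2.33%) or between feedings in NTG (0, 2.84%). Predicted genes and Riken clones aside, the smallest p were those of Agpat2, the expressed sequence AW495222, Gipr, Tmem97 and Nrg2 between genotypes, of Kank2, Cdkn1a, Cilp2, Adra2a and Fibin between feedings in TG, and of Insc, Pdk4, Arid5a, Natd1 and Ccbe1 between feedings in NTG, none past the threshold (adjusted p of at least 0.995). No list's change differed past the threshold with an estimated correlation in these 3 comparisons either. For the glucocorticoid list, the change on TRF minus that on ALF in TG had a median of 0.37 (adjusted p = 0.130 with an estimated correlation). Of its values 21 of 22 were positive, with Cdkn1a at 1.46 ± 0.39 and Angptl4 at 1.59 ± 0.48. For the homeostatic microglia list the same difference had a median of −0.24, with 16 of 16 values negative (adjusted p = 0.130 with an estimated correlation). For the immediate early genes the median difference in change was 0.36 between genotypes on ALF and 0.39 between feedings in NTG. Neither was past the threshold (adjusted p = 0.326 and 0.323 with an estimated correlation).

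**Figure D5:**
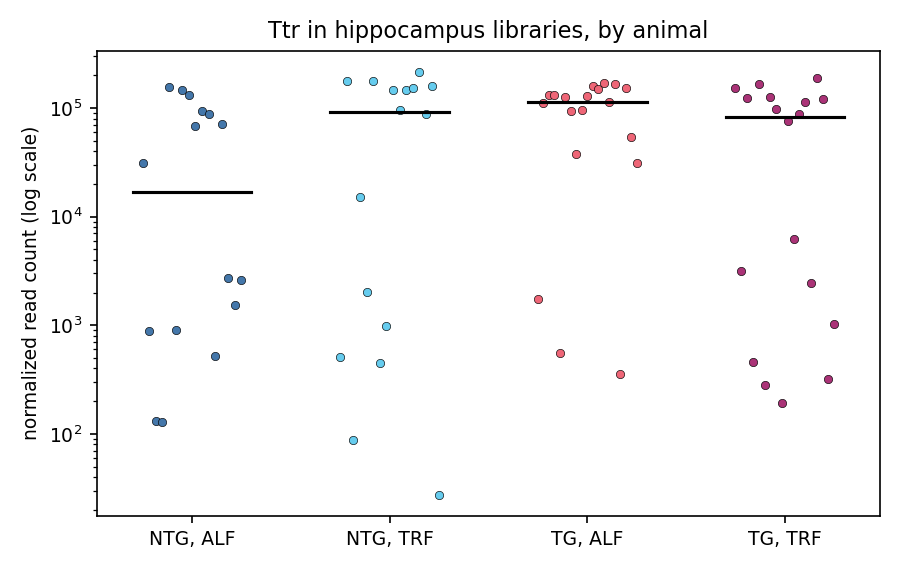
Normalized read counts of Ttr, the most abundant transcript of choroid plexus, in each of the 69 animals (points, log axis), by genotype and feeding, with the group median (bar). Values range from 27.6 to 215418, and 16 animals have fewer than 1000 counts, 5 in NTG on ALF, 5 in NTG on TRF, 2 in TG on ALF and 4 in TG on TRF.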

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

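The tests of the covariance against choroid plexus tissue, of the cholesterol genes against glial markers and the myelin level, and of time with the number series in the model were chosen only after the result was seen. For Bmal1, Dbp, Ciart, Per2, Nr1d1, Rbm3 and Hspa5, 77 groups of values were searched for a single far animal, and 6 had one. Chance gives about 1 in 20 such groups. Bmal1 was lowest in replicate 10 of NTG on TRF at ZT12 (750.1 against 909 in the nearest of 6 animals), and the same animal was highest in Ciart (1010 against 781). Dbp was low in replicate NTG_ALF_107 at ZT0 (382 against 900 in the nearest of 7) and high in TG_TRF_129 at ZT0 (1115 against 842, of 6). Rbm3 was high in NTG_ALF_120 at ZT0 (1999.6 against 1606, of 7) and in TG_TRF_307 at ZT6 (3760 against 2640, of 4). No cause of these values was tested.

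Each count of genes was set against 100 splits of the same animals, the real one included. For TG against NTG on TRF the real count was 19 and the highest other 1, for TRF against ALF in TG 77 and 1, and for time of sacrifice 5073 and 3. For the change from ZT0 to ZT12 it was 85 and 58 in NTG on TRF, 316 and 87 in TG on ALF, and 506 and 424 in TG on TRF. In each of these 6 comparisons 1 split, the real one, reached the count. That argues against a random grouping of the animals as the whole source of these counts. With 100 splits, not corrected for the number of comparisons, chance is not excluded. Splits also cannot rule out a chance imbalance of tissue between the groups. For 3 other comparisons fewer than 5 of 100 splits reached the count, again not corrected for the number of comparisons. These were TG against NTG on ALF (27, with 2 splits as large and a highest other of 1249) and TRF against ALF in NTG (4, with 3 as large and 1726). The third was the change in NTG on ALF (310, with 2 as large and 2508). Chance is not excluded for any of the 3. The evidence is weakest for the 4 genes, since leaving out any of 4 single animals, or the 5 libraries of lowest correlation with the others, also ended all calls. In these 3 the highest other split called many times the real count, which points to a structure among the samples other than the study's groups, and so do the highest splits of 2 differences in change given next (1562 and 2210). These 3 comparisons and those 2 differences all include NTG on ALF, as does the interaction, whose highest other split was 1. NTG on ALF holds the 2 libraries of lowest correlation with the others, NTG_ALF_107 (median r = 0.940) and NTG_ALF_1 (0.952), both at ZT0. Whether those splits follow these libraries was not tested. The interaction (0, highest other 1) and the differences in change between genotypes on ALF (0 and 1562), between feedings in TG (0 and 1) and between feedings in NTG (0 and 2210), had real counts of 0, which each of the 100 splits reaches by construction, so these splits say nothing about chance.

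The feeding effect in TG ran against the genotype effect on ALF, with a covariance of −0.0082 across genes. Leaving out the genes of the choroid plexus, ependyma and meninges lists left it at −0.0051, so these genes alone do not account for it. Removing the level of the choroid plexus list from every gene turned it to 0.0027, and 95 of 100 permutations were as low. A candidate explanation is that the amount of choroid plexus in the dissection, with whatever varies along with it, differed by chance between the groups. Median Ttr was 16823 in NTG on ALF, 112994 in TG on ALF and 82627 in TG on TRF, so its medians lay closer for the feeding effect than for the genotype effect. A reversal of transgene effects by feeding stays open. A single covariance over all genes cannot exclude a reversal in part of them. A reversal that also moved choroid plexus genes would be removed along with their level, and that was not tested.

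The genes of cholesterol synthesis were higher in TG under both feedings. With the choroid plexus level as a covariate 12 of them still passed on ALF, and with the animals' number series as a covariate also 12, which argues against choroid plexus tissue and cohorts as the whole cause. With the myelin level as a covariate the number was 12 as well. Levels of thalamus, striatum, neocortex and meninges were not fitted as covariates. More astrocytes or oligodendrocytes would raise their markers, but the highest of those lists' medians in TG was 0.0092. An effect of the transgene stays open and was not tested beyond the comparison itself.

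Time of sacrifice is partly tied to the number series, since the ZT6 and ZT18 animals are all of the 300 series, while the ZT0 and ZT12 animals hold the series in similar numbers. The changes from ZT0 to ZT12 and from ZT6 to ZT18 called 78.8% of the genes without a series term, and 82.3% with the number series in the model, while 4090 genes passed without the 5 libraries of lowest correlation with the others. These values argue against cohorts or those libraries as the whole cause. A daily rhythm may explain the pattern, as a hypothesis, although each animal gives 1 time and 1 cycle was sampled.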

How the results depend on the processing

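Chosen only after the data were seen were the voom weights, the filter on a mean of at least 200, both tissue covariates, the fits without 5 libraries and both covariance settings on choroid plexus; the other settings were planned. No named gene reversed in 2344 gene and setting pairs, of which 2110 kept their side of the threshold and the rest lost it. Most of these genes were named for passing in the main fit of the same animals, which favours a kept direction. The losses were uneven. Of the 77 genes of TRF against ALF in TG, 20 still passed with the choroid plexus covariate, 7 with the myelin covariate and 7 without 5 libraries. Of the counts of genes under other settings, those with a planned value of 0 left out, 77.4% stayed within 1.5 times. The interaction and the 3 differences in change stayed at 0 throughout. TG against NTG on ALF (27) was 94 with array weights; on TRF (19) it was 40 with array weights and 12 with ZT0 and ZT12 animals only. TRF against ALF in TG (77) was 123 with quantile normalization, 3.0e+02 with array weights, 0 with ZT0 and ZT12 only (unadjusted 1280, limma), 3 with 16 cell means, 2 with no time term, 173 with only the 2 groups, 7 without 5 libraries, 20 with the choroid plexus and 13 with the myelin covariate. In NTG (4) these gave 2 (quantile), 10 (array weights), 14 (cell means), 0 (no time term, unadjusted 968, limma), 2 (only 2 groups), 0 (without 5 libraries, unadjusted 1027) and 1 (myelin), with 2 for the number series and 0 for voom (unadjusted 987). ZT12 against ZT0 in NTG on ALF (310) was 619 with the number series and 130 without 5 libraries; in NTG on TRF (85) 191 with array weights and 143 without 5 libraries; in TG on ALF (316) 201 with voom and 1.3e+02 without 5 libraries; in TG on TRF (506) 1079 with array weights. The covariance reversed to 0.0027 with the choroid plexus score removed. Of 420 list tests 143 passed camera at the preset correlation, 17 at an estimated one and 36 by fry. The cosine passed for 18 clock genes over all animals and for 7 in NTG on ALF and 10 in NTG on TRF. TRF against ALF in TG turned from mostly lower to mostly higher with the number series (31 and 21), the myelin covariate (11 and 2) and without 5 libraries (5 and 2), and in 2 settings with at most 3 genes. The cause of these shifts was not tested, except that single groups hold fewer animals. The tests planned in edgeR and DESeq2, on whole reads if these could be recovered, were not run, because the low values alone showed the step in only 2 of 70 libraries; voom on the whole multiples was run.

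Leaving out 1 animal gave 22 to 40 genes for genotype on ALF, 15 to 24 on TRF and 4548 to 5444 for time. For feeding in TG it gave 18 (TG_TRF_104) to 248 (TG_TRF_24); the others that moved it over 1.5 times were TG_ALF_5 (21), TG_TRF_307 (26), TG_ALF_16 and TG_TRF_330 (28), TG_ALF_304 (35), TG_ALF_124 (39), TG_ALF_332 (40), TG_ALF_115 (42), TG_ALF_314 (43), TG_ALF_310 and TG_ALF_319 (45), TG_TRF_7 (47), TG_ALF_234 (119) and TG_TRF_102 (172). For feeding in NTG it gave 0 to 8 (NTG_ALF_328), with 0 without NTG_ALF_3, NTG_ALF_135, NTG_ALF_101 or NTG_ALF_301, and 20 of 32 animals moved it. For ZT12 against ZT0 it gave 147 (NTG_ALF_1), 166 (NTG_ALF_322), 185 (NTG_ALF_106, NTG_ALF_107), 565 (NTG_ALF_134) and 595 (NTG_ALF_136) in NTG on ALF; 53 (NTG_TRF_8), 54 (NTG_TRF_32), 55 (NTG_TRF_142) and up to 97 in NTG on TRF; 1.1e+02 (TG_ALF_16), 143 (TG_ALF_23), 1.5e+02 (TG_ALF_5), 174 (TG_ALF_13), 181 (TG_ALF_125) and up to 457 in TG on ALF; and 236 (TG_TRF_104), 3.1e+02 (TG_TRF_321 or TG_TRF_121) and up to 680.0 in TG on TRF.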

Other observations

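The tests at single times of sacrifice were chosen only after the data were seen. At ZT12, lights off and of the 4 times the longest after food on TRF, the glucocorticoid list was higher on TRF than on ALF in TG mice, with 22 of 22 values positive and a median of 0.55 (camera adjusted p = 0.0016 with an estimated correlation, n = 5 and 6, limma). No member passed over all genes there, and Cdkn1a was at 1.2 ± 0.28, Sult1a1 at 1.01 ± 0.22, Fkbp5 and Gjb6 at 0.53 ± 0.12. In NTG mice at ZT12 22 of 22 values were positive too, with a median of 0.30 (adjusted p = 0.069 with an estimated correlation). In TG at ZT6 20 of 22 values were positive with a median of 0.36, at ZT0 17 with 0.15 and at ZT18 17 with 0.13 (adjusted p = 0.745, 0.631 and 0.748 with an estimated correlation), and in NTG at ZT0 16 with 0.19 (0.734). Whether the times differ was not tested here, except for ZT12 against ZT0, where no difference passed with an estimated correlation (0.130 in TG). The homeostatic microglia list was lower on TRF in TG at ZT12, with a median of −0.20 and 1 member called (adjusted p = 0.033 with an estimated correlation).

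The genotype difference in cholesterol synthesis appeared at single times as well. In TG against NTG the list's median was 0.26 at ZT0 and 0.35 at ZT12 on ALF (adjusted p = 0.0035 and 3.6e-08 with an estimated correlation), and 0.28 and 0.21 on TRF (8.2e-06 and 0.0028).

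Other lists did not pass with an estimated correlation in any of the 12 comparisons. Their lowest adjusted p were 0.130 for fat oxidation and ketone metabolism, 0.130 for meninges and fibroblasts, 0.130 for interneurons, 0.135 for reactive astrocytes, 0.332 for striatum, 0.359 for ependyma, 0.438 for blood, 0.535 for thalamus, 0.543 for pericytes and smooth muscle, 0.554 for CA1, 0.57 for synapse, 0.604 for neocortex, 0.617 for neuropeptides and neurotrophins, 0.676 for RNA quality, 0.687 for CA3 and 0.760 for lysosome and autophagy. For the dentate gyrus list it was 0.215.

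The 2 libraries read as 1 animal of NTG on TRF at ZT12 differed by 140.4 in chi-square per degree of freedom, within the 14.3 to 168 of different animals in the same group and time. The difference in Rn45s between both libraries (0.34% and 4.63%) weighs heavily in that value. The r of the 2 libraries, 0.9921, was near the top of the range of those other pairs, 0.9751 to 0.9924. The SD of their log2 difference, 0.269, was near the bottom of that range, 0.262 to 0.477.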
